A study of Homo sapiens with 9 samples.

How the data were processed

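RNA of T84 and Caco-2 cells was extracted with Trizol, and biotin-labelled cRNA made from 0.5 ug of total RNA was hybridised to single-colour arrays of the Affymetrix type. Untreated T84 cells (passage 68) and Caco-2 cells (passage 37) were grown to 90% confluence in 6-well plates. Treated T84 cells received 100 U/ml interferon gamma for 24 hours, and their passage, confluence and plates are not given in the sources used here. The deposited values were log2 signals per probe set, which the authors had summarised and normalized between arrays by RMA. The version of RMA, the probe sets that entered it and any later filter are not given in the sources used here. The values were used as deposited, without further normalization.

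The table held 1259 probe sets and no control probe sets. Of these, 1069 carried a RefSeq identifier, 189 a UCSC identifier and 1 another. A RefSeq table matched by identifier without its version gave exactly 1 symbol to 1043 probe sets and none to 216, which stayed in every test without a gene name. The 1043 stood for 927 genes, 93 of which had more than 1 probe set, and a gene was represented by its probe set with the highest mean over all arrays. By their suffixes, 266 probe sets are shared among transcripts, 113 among transcripts of a gene, and 87 can cross-hybridise, so a symbol on the first or last kind may stand for related genes. No positions are given, because the sources used here do not name the genome build of the probe sets.

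The arrays formed 3 groups of 3 by their labels: treated T84, untreated T84 and untreated Caco-2. One linear model with the group as its single factor was fitted to all 9 arrays with limma 3.58.1 in R 4.3.3, followed by moderation (6 residual and 2.12 prior degrees of freedom). Each pair of groups was compared, with Benjamini-Hochberg adjustment over 1259 probe sets and a threshold of 0.05 on the adjusted p. Errors of fold changes are standard errors of this fit, intervals are at 95%, and errors of group means are standard deviations. Probe sets past the threshold against both untreated T84 and Caco-2 in 1 direction were counted and set beside the number that independent lists would share and beside 100 simulations of unchanged groups.

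Of 26 gene lists written in advance, with 619 members of which 405 were measured, the 25 with at least 5 measured genes were tested with camera (correlation preset to 0.01, two-sided, Benjamini-Hochberg over the 25 lists). Camera with an estimated correlation and the self-contained test fry were run beside it. List members were also counted after adjustment over the list alone.

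Genes were named by a rule set in advance. It took the 10 largest changes in each direction of each comparison among those past the threshold with groups that did not overlap. It added CD44, all measured sialyltransferase genes and genes of sialic acid supply and removal, up to 4 members of other lists by adjusted p, and the 10 largest changes against both others. Members of other families named in the last part were chosen after their values were seen.

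The fit was tested on simulated data with 200 of 1259 probe sets changed, 20 times. It called 52.2, 83.3, 95.2 and 98.8% of changes of 0.25, 0.5, 1 and 2 log2 units, and 4.3% of its calls were unchanged probe sets. A shifted list was called in 20 of 20 simulations, with 1 call in 440 tests of unshifted lists. The simulated noise was independent between probe sets, whereas correlations estimated within the lists of these data reached 0.566. The simulated rates therefore need not hold for these data. The array number limits the precision.

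Alternatives covered the arrays in the fit, a replicate block, moderation, array weights, scaling, filters on dim probe sets, thresholds, the choice of probe set, single arrays left out, and the set tests. After the data were seen, 3 were added: leaving out 3 arrays together, a covariate for their shared deviation, and centring on ribosomal protein genes. Figures were drawn with matplotlib 3.10.9, and tables were handled with pandas 2.3.3 in Python 3.11.15. Splice variants of CD44 and probe sets without a symbol were not analysed here as genes.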

Results

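Glycosylation-related transcripts were measured in 2 human colon carcinoma-derived epithelial cell lines, T84 and Caco-2, on 9 single-colour arrays of 1259 probe sets. T84 cells were either treated with 100 U/ml interferon gamma, a cytokine released by activated T and natural killer cells, for 24 hours (3 arrays) or left untreated (3 arrays). Untreated Caco-2 cells made up the other 3 arrays. The series asked which glycosylation genes could contribute to the rise of a sialylated CD44 variant epitope, recognised by the antibody GM35, in T84 cells given interferon gamma, with Caco-2 as a line that lacks the epitope. The labels number the replicates without saying whether they came from separate cultures, so the p-values measure only the spread between these samples, which may be technical. The number of arrays, 3 per group, limits the precision. The median standard error of a log2 fold change was 0.077 in each comparison, the same because the spread was estimated over all 9 arrays together. Within groups the median SD was 0.064 in treated T84, 0.071 in untreated T84 and 0.1 in Caco-2. Tests of treated against untreated T84 therefore also carry the spread of Caco-2. Array medians lay between 6.7 and 6.8 log2 units. Correlations across probe sets, which are not independent replicates, ran from 0.987 to 0.999 within groups, from 0.981 to 0.987 between treated and untreated T84, and from 0.903 to 0.932 between T84 and Caco-2. The first 3 principal components held 81.7, 9.6 and 6.2% of the variance. The first parted the lines, the second parted treated from untreated T84, and the third set Caco-2 replicate 1 farthest from the other Caco-2 arrays.

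The first comparison asked what interferon gamma changed within T84 cells. Chemokine genes showed the largest rises. CXCL9, a ligand of the chemokine receptor CXCR3 on T cells, rose from a log2 signal of 5.79 ± 0.12 to 11.92 ± 0.49 (SD, n = 3 each), or 69.8-fold (95% confidence interval 50.0 to 97.3). CXCL10 and CXCL11, ligands of the same receptor, rose 34.5-fold (29.5 to 40.4) and 16.4-fold (10.3 to 26.2). CD74, the invariant chain of MHC class II, rose 11.7-fold, TNFSF13B, which encodes the B cell survival factor BAFF, 10.7-fold, the leukocyte adhesion molecule ICAM1 8.97-fold, and the membrane-anchored chemokine CX3CL1 5.16-fold. The mucin gene MUC4 rose 2.67-fold, CXCL2 2.58-fold and CCL5 2.55-fold. The probe set of CXCL2 can cross-hybridise with related genes, and its other probe set, without that suffix, rose by 1.2 ± 0.19 log2 units (SE). All of these had adjusted p values at or below 0.00717 in the moderated test of limma (Benjamini-Hochberg over 1259 probe sets, n = 3 per group).

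The falls were smaller. FGFR3, a fibroblast growth factor receptor gene, showed the largest, from 8.93 ± 0.12 to 7.69 ± 0.10 (SD, n = 3), a log2 fold change of -1.24 ± 0.11 (SE; limma adjusted p = 0.000207). The chemokine gene CCL20 followed at -1.16 ± 0.18, the orphan transporter gene SLC35D3 at -1.12 ± 0.09 and the glucuronosyltransferase gene UGT1A1 at -1.11 ± 0.08. The UGT1A1 probe set is shared among transcripts and may also read other UGT1A family members. IHH, a hedgehog ligand gene, fell by 1.06, PAPSS2, which makes the sulfate donor of sulfotransferases, by 1.04, and IGFBP1 by 1.03. GNE fell by 1.02, the frizzled receptor gene FZD2 by 0.96 and IGF1R by 0.88. All 10 had adjusted p values at or below 0.00858 in limma with n = 3 per group. The IGFBP1 call was lost, at a log2 fold change of -1.06 and an adjusted p of 0.069, when 3 arrays that deviated together from their groups were left out, a check chosen after seeing the data.

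Of the 20 measured sialyltransferase genes, 1 rose, 2 fell and 17 did not pass the test. The counts were the same when adjusted over the list alone. ST6GALNAC2, which adds sialic acid to the GalNAc of O-glycans, rose from 6.57 ± 0.14 to 7.81 ± 0.09 (SD, n = 3), or 2.36-fold (95% confidence interval 1.94 to 2.88; limma adjusted p = 0.000405). ST6GALNAC1, which acts on the same residue and makes the sialyl-Tn antigen, fell 1.35-fold (1.25 to 1.46; adjusted p = 0.000916). ST3GAL4 fell 1.46-fold (1.23 to 1.74; adjusted p = 0.0139 in limma, n = 3 per group). That call was lost without treated replicate 1, treated replicate 2 or untreated T84 replicate 3, at adjusted p values of 0.0543, 0.0589 and 0.0573. ST6GAL1, the main alpha-2,6 sialyltransferase of N-glycans, had a log2 fold change of -0.30 ± 0.09 that did not pass (adjusted p = 0.0955), ST3GAL2 one of -0.22 ± 0.08 and ST6GALNAC5 one of -0.27 ± 0.11. The other 14 lay between -0.10 and 0.12. By the competitive set test camera, the list did not differ from the other genes (adjusted p = 0.592).

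Among 13 genes of sialic acid supply and removal, GNE alone passed, and it fell. GNE encodes the bifunctional enzyme that starts sialic acid synthesis from UDP-GlcNAc. Its log2 signal went from 9.70 ± 0.09 to 8.68 ± 0.20 (SD, n = 3; 2.02-fold lower, 95% confidence interval 1.68 to 2.43; limma adjusted p = 0.000757). The CMP-sialic acid synthetase gene CMAS was at -0.32 ± 0.16, the sialic acid transporter genes SLC35A1 and SLC17A5 at 0.41 ± 0.23 and -0.39 ± 0.12, and the sialidase gene NEU1 at -0.39 ± 0.12. None of these 4 passed. Adjusted over the list alone, the count was again 0 higher and 1 lower (camera adjusted p = 0.575). CD44 itself had a log2 fold change of -0.29 ± 0.11 (9.99 ± 0.09 against 10.28 ± 0.12, SD, n = 3; limma adjusted p = 0.181). Its single named probe set does not tell splice variants apart, so the variant exon v6 was not analysed here.

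**Figure D1:**
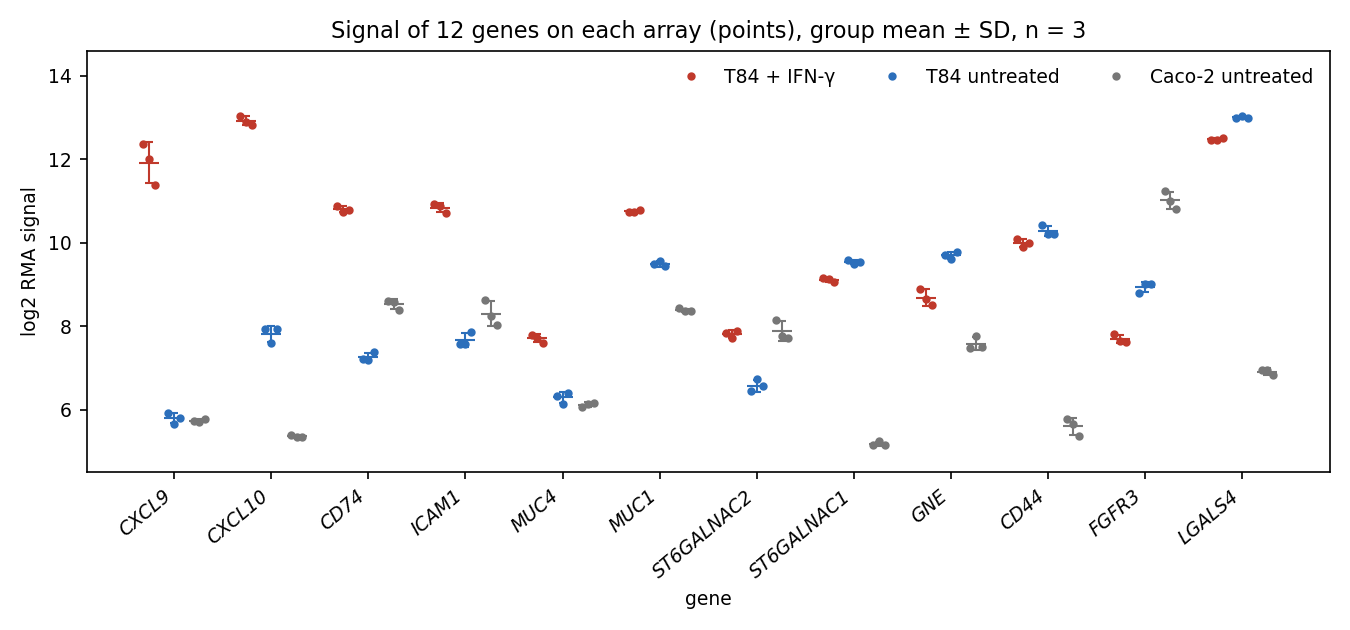
Log2 RMA signal (vertical axis) of 12 genes on each of the 9 arrays, as points, with the group mean and SD (n = 3) as a bar and whiskers. CXCL9, CXCL10, CD74, ICAM1, MUC4 and MUC1 are highest in treated T84, ST6GALNAC2 in treated T84 (7.81) lies near Caco-2 (7.87), and GNE in treated T84 (8.68) lies between untreated T84 (9.70) and Caco-2 (7.58).

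**Figure D2:**
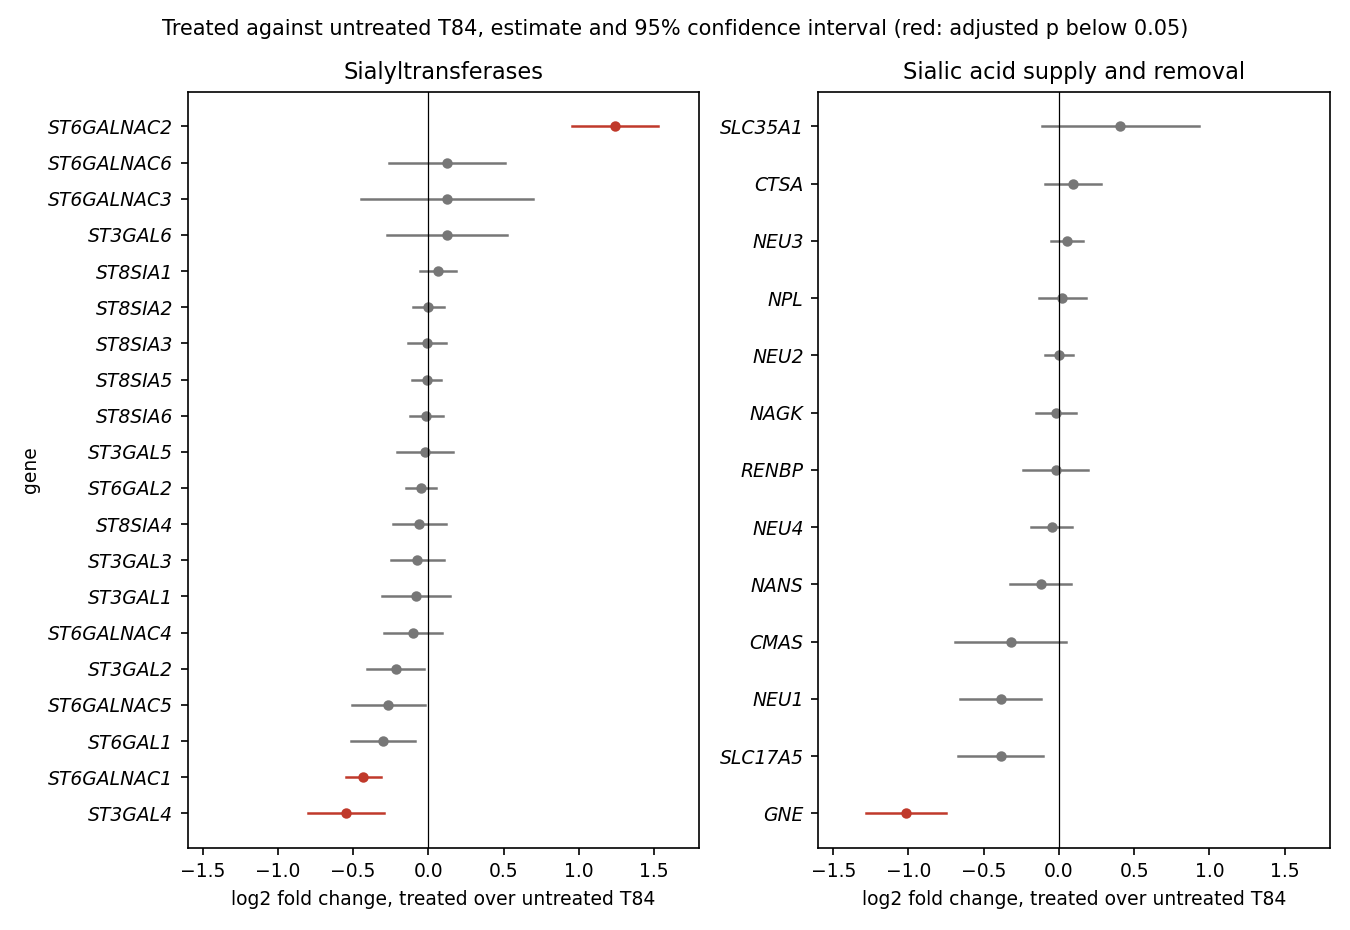
Log2 fold changes of treated over untreated T84 (horizontal axis, points) with 95% confidence intervals (lines) for 20 sialyltransferase genes and 13 genes of sialic acid supply and removal. Red marks an adjusted p below 0.05: ST6GALNAC2 (1.24) lies to the right, and GNE (-1.02), ST3GAL4 (-0.55) and ST6GALNAC1 (-0.43) to the left.

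The fixed list of interferon gamma response genes moved most. Of its 18 measured members 12 rose, 1 fell (CCL20) and 5 did not pass, with the same counts adjusted over the list alone (camera adjusted p = 4.37e-14; adjusted p = 0.146 with an estimated correlation). The 5 included both interferon gamma receptor genes. Of 37 chemokine genes 11 rose and 1 fell, with the same counts adjusted over the list alone (camera adjusted p = 5.1e-06; adjusted p = 0.664 with an estimated correlation). These 2 lists share members, and neither call held with the estimated correlation. The test fry, which does not compare a list with the other genes, called both (adjusted p = 9.2e-06 and 0.00109). Of 14 mucin genes, 3 rose and none fell: MUC4, MUC1 (2.39-fold, 2.21 to 2.58, limma adjusted p = 9.74e-07, n = 3 per group) and MUC13 (1.32-fold, 1.17 to 1.49). Adjusted over the list alone, 4 rose. The median of the mucin list was -0.04 and its mean 0.19. Camera gave an adjusted p of 0.22 and fry one of 0.00109.

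The glycan-modifying lists are small, and their counts stand beside 10.2% of all 1259 probe sets past the threshold in this comparison. The 12 galectin genes had 3 higher and 1 lower (4 and 1 adjusted over the list alone), with LGALS9 at 0.44 ± 0.06 and the intestinal galectin gene LGALS4 at -0.53 ± 0.05. HK1, the hexokinase gene counted with nucleotide sugar supply, rose 2.17-fold (1.85 to 2.54), and PGM1 of the same list fell 1.55-fold (1.36 to 1.76). That list had 1 higher and 2 lower of 24. The heparanase gene HPSE rose 1.63-fold (1.34 to 1.99), and FUT4, a fucosyltransferase gene, 1.47-fold (1.26 to 1.73). The lysosomal alpha-fucosidase gene FUCA1 fell 1.60-fold (1.35 to 1.90) and the beta-mannosidase gene MANBA 1.39-fold (1.24 to 1.55). Among cytokine and growth factor receptors, 2 rose, IL2RG (1.95-fold) and IL10RA (1.44-fold), and 5 of 35 fell, FGFR3 and IGF1R among them. Counts higher and lower were 0 and 3 of 24 for lysosomal and other glycosidases, 0 and 3 of 19 for the N-glycan precursor and oligosaccharyltransferase list, and 0 and 3 of 18 for other sulfotransferases. They were 1 and 1 of 18 for fucosylation, 1 and 1 of 32 for heparan sulfate synthesis, and 1 and 0 of 15 for chondroitin and dermatan sulfate synthesis. They were 0 and 2 of 18 for O-GalNAc initiation, 0 and 2 of 25 for chain extension (0 and 1 over the list alone), 0 and 2 of 18 for glycolipids, 1 and 2 of 19 for cell surface proteoglycans, and 0 and 1 of 9 for GPI anchors. No member passed in O-glycan core synthesis (9), N-glycan trimming and branching (14), ABO-related glycosylation (7) or hyaluronan and its receptors (8). No member passed either among 15 leukocyte markers or among 12 fibroblast and endothelial markers. Camera called none of these lists, and its smallest adjusted p among them was 0.0508. Among them fry called cell surface proteoglycans and GPI anchors (adjusted p = 0.0144 for each). Several of the counts above held calls near the threshold, which were lost when single arrays were left out. Without treated replicate 2, the calls of CLC, PMM1, ALG14, DPM3, PAPSS1, MFNG, GALC, GM2A, SDC1 and HSPG2 were lost (limma adjusted p from 0.058 to 0.169). Each of these calls was also lost without at least 1 other array, so the losses do not single out treated replicate 2. PMM1, PAPSS1, MFNG and GM2A were lost even without Caco-2 replicate 2, which is outside this comparison (0.0685 to 0.0766). GM2A kept a log2 fold change of -0.62 without treated replicate 2, against -0.64 in the main fit. The call of CHSY1 in the chondroitin list was lost without treated replicate 1 or untreated T84 replicate 1 or 3 (0.051 to 0.0878). Epithelial adhesion had only 2 measured members, ICAM1 and CD44, and was not tested as a set. Adjusted over these 2 alone, ICAM1 was higher and CD44 lower. That CD44 call rests on an adjustment over only 2 genes. CD44 did not pass over all 1259 probe sets, nor when adjusted over the 8 genes of hyaluronan and its receptors alone.

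Over all 1259 probe sets, 55 were higher and 73 lower in treated than in untreated T84 at a limma adjusted p below 0.05 (n = 3 per group), 19 and 9 of them by at least 2-fold. The 2 groups did not overlap at 346 probe sets (27.5%, where chance gives 10%). Fitting only the 6 arrays of these 2 groups gave 65 higher and 101 lower, and leaving out Caco-2 replicate 1 gave 70 and 108. Without treated replicate 2, treated replicate 3 or untreated T84 replicate 3, the number lower was 40, 48 or 44, while other settings stand in the closing section. With each array centred on ribosomal protein genes, a scaling chosen after seeing the data that shifts the median log2 fold change from -0.01 to 0.05, the calls were 54 higher and 43 lower.

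The second comparison set treated T84 against Caco-2, the epitope-negative line, and the third set untreated T84 against Caco-2. CD44 was higher than in Caco-2 by a log2 fold change of 4.39 ± 0.11 (SE) in treated T84 and of 4.68 ± 0.11 in untreated T84 (25.6-fold, 95% confidence interval 21.5 to 30.4). Its log2 signal in Caco-2 was 5.60 ± 0.21 (SD, n = 3). ST6GALNAC1 was 15.2-fold (14.0 to 16.5) and 20.5-fold (18.9 to 22.2) higher. GNE was 2.14-fold higher than Caco-2 in treated T84 (1.78 to 2.57) and 4.33-fold higher in untreated T84 (3.61 to 5.20). ST6GALNAC2 was 2.47-fold lower in untreated T84 than in Caco-2 (2.02 to 3.01; limma adjusted p = 4.23e-05, n = 3 per group), while treated T84 differed from Caco-2 by a log2 fold change of -0.06 ± 0.12 (adjusted p = 0.71).

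In treated T84 against Caco-2, 2 of 20 sialyltransferase genes were higher, 7 lower and 11 not past the test. These and the later list counts against Caco-2 stand beside the share of all 1259 probe sets past the threshold. That share was 45.6% for treated and 43.7% for untreated T84, and the sialyltransferase counts lie near it. ST6GALNAC1 and ST6GALNAC5 (log2 fold change 0.41 ± 0.11) were higher. ST3GAL6 was lower by a log2 fold change of -3.05 ± 0.17, ST6GALNAC3 by -2.96 ± 0.25, ST3GAL1, which sialylates core 1 O-glycans, by -1.42 ± 0.10 and ST6GALNAC6 by -1.40 ± 0.17. ST6GALNAC4 was at -0.66 ± 0.08, ST3GAL2 at -0.38 ± 0.08 and ST3GAL3 at -0.23 ± 0.08, also past the test. The other probe set of ST3GAL2 did not pass (-0.11 ± 0.10), so that call rests on 1 of 2 probe sets. The ST3GAL3 call (adjusted p = 0.0348 in limma, n = 3 per group) was lost without any of 6 arrays, at adjusted p values up to 0.118 without treated replicate 1. Its direction turned (0.03) with ribosomal centring, which also ended the ST3GAL2 call. In untreated T84 against Caco-2, 4 were higher, 6 lower and 10 not past the test, with ST3GAL4 (0.68 ± 0.11) and ST6GAL1 (0.44 ± 0.09) among those higher. Counts adjusted over the list alone were the same in both comparisons. Camera gave adjusted p values of 0.684 and 0.798 for the list. With ribosomal centring the counts were 12 higher and 5 lower in the first and 12 and 6 in the second.

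Of the 13 sialic acid supply and removal genes, 3 were higher and 5 lower in treated T84 than in Caco-2, and 3 and 4 in untreated T84, with the same counts adjusted over the list alone. SLC35A1, the Golgi CMP-sialic acid transporter gene, was higher by 1.41 ± 0.23 and 1.00 ± 0.23 log2 units, and NEU1, read by a probe set that may cross-hybridise, lower at -1.45 ± 0.12 and -1.06 ± 0.12. The sialic acid lyase gene NPL was lower at -1.08 ± 0.07 and -1.11 ± 0.07. With ribosomal centring 7 were higher and 3 lower in each. The list did not stand out in camera (adjusted p = 0.684 and 0.798).

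Among the 10 largest differences in each direction between treated T84 and Caco-2, CXCL10 was 189-fold higher (162 to 221), CXCL9 72.6-fold, CXCL11 59.7-fold, LGALS4 47.3-fold (43.7 to 51.2), the lysosomal glycoprotein gene LAMP3 25.4-fold, CCL5 16.1-fold and TNFSF13B 15.5-fold. The proteoglycan gene GPC4 (14.7-fold) completed the 10 largest together with CD44 and ST6GALNAC1. Lower were the fetal growth factor gene IGF2 (86.7-fold, 77.9 to 96.6), the galectin gene LGALS2 (53.0-fold), FGFR2 (33.0-fold), the plasma glycoprotein gene AHSG (32.3-fold), PDGFC (31.2-fold), GPC3 (31.0-fold), PTN (27.5-fold), the asialoglycoprotein receptor gene ASGR2 (12.6-fold), the I-branching enzyme gene GCNT2 (10.9-fold) and BMP7 (10.3-fold). Each of these 20 had a limma adjusted p at or below 1.52e-06 (n = 3 per group). Interferon gamma response genes had 15 higher and 1 lower of 18 (camera adjusted p = 9.03e-07; adjusted p = 0.715 with an estimated correlation). Chemokine genes had 17 higher and 3 lower of 37 (camera adjusted p = 0.000212; adjusted p = 0.732 with an estimated correlation). Both counts were the same adjusted over the list alone.

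Over all probe sets, 244 were higher and 330 lower in treated T84 than in Caco-2 (limma adjusted p below 0.05, n = 3 per group), 94 and 121 by at least 2-fold, and 674 (53.5%, against 10% by chance) had groups that did not overlap. Centred on ribosomal protein genes, whose median log2 fold change was -0.28 here, the median of all probe sets moved from 0.02 to 0.29 and the calls became 779 higher and 220 lower, so small differences from Caco-2 depend on the scaling.

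In untreated T84 against Caco-2, LGALS4 was 68.5-fold higher (63.2 to 74.1), UGT1A1 26.6-fold, GPC4 13.4-fold, the interferon-induced membrane protein gene IFITM1 13.2-fold, the stress cytokine gene GDF15 11.9-fold, LAMP3 11.3-fold, the Lewis fucosyltransferase gene FUT3 9.66-fold and the galectin-3 binding protein gene LGALS3BP 9.28-fold. IGF2 was 98.7-fold lower (88.6 to 110), LGALS2 49.4-fold, AHSG 32.4-fold, GPC3 31.2-fold, FGFR2 29.9-fold, PTN 28.6-fold, PDGFC 24.9-fold, ASGR2 12.1-fold, GCNT2 11.9-fold and IGFBP3 11.8-fold. PTN is read by a probe set that may cross-hybridise. Each of these 18, CD44 and ST6GALNAC1 had a limma adjusted p at or below 1.28e-06 (n = 3 per group). Interferon gamma response genes had 10 higher and 3 lower of 18, again the same adjusted over the list alone (camera adjusted p = 0.0429; adjusted p = 0.754 with an estimated correlation). CXCL10 was 5.47-fold higher without any treatment and CD74 lower by a log2 fold change of -1.27 ± 0.08. Chemokine genes had 12 higher and 3 lower of 37, also over the list alone (camera adjusted p = 0.0322; adjusted p = 0.754 with an estimated correlation).

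Glycolipid genes had 0 higher and 8 lower of 18 in untreated T84, among them the lysosomal hydrolase genes GLB1 (-0.89 ± 0.09) and ARSA (-0.83 ± 0.08), and mucin genes 5 higher and 2 lower of 14 (6 and 2 over the list alone), among them MUC13 (2.07 ± 0.07) and MUC20 (3.49-fold higher). Of all 1259 probe sets, 43.7% passed in this comparison. Camera called neither list (adjusted p = 0.101 for each), and with ribosomal centring the counts were 3 and 7 for glycolipid and 12 and 0 for mucin genes. Fibroblast and endothelial markers had 0 higher and 5 lower of 12, with PDGFRA at -1.63 ± 0.24 and PECAM1 at -0.62 ± 0.06, and leukocyte markers 2 higher and 1 lower of 15, while ribosomal centring gave 6 and 5 and 11 and 0. In all, 245 probe sets were higher and 305 lower in untreated T84 than in Caco-2 (limma adjusted p below 0.05, n = 3 per group), 88 and 106 by at least 2-fold, and 49.6% had groups that did not overlap, against 10% by chance. The ribosomal scaling, which moved the median of all probe sets from 0.02 to 0.22, gave 680 and 214.

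The design also asked which genes stood higher in treated T84 than in both others. There were 43 such probe sets, representing 33 genes by their main probe set. The 10 largest by the smaller of the 2 fold changes were CXCL9 (69.8-fold), CXCL10 (34.5-fold), CXCL11 (16.4-fold), TNFSF13B (10.7-fold), ICAM1 (5.83-fold), CX3CL1 (5.16-fold), CD74 (4.84-fold), MUC4 (2.67-fold), CXCL2 (2.58-fold) and CCL3 (2.55-fold), whose probe set may also read related genes. No sialyltransferase gene and no gene of sialic acid supply or removal was among them. ST6GALNAC2 was higher than in untreated T84 only, and GNE was lower than in untreated T84 and higher than in Caco-2.

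Lower in treated T84 than in both others were 44 probe sets, or 33 genes. FGFR3 (2.36-fold), IHH (2.08-fold), FZD2 (1.95-fold), IGF1R (1.76-fold), the galactosylceramidase gene GALC (1.67-fold), the O-GalNAc transferase gene GALNT11 (1.61-fold), SULT1A2 (1.61-fold), BMP7 (1.60-fold), FUCA1 (1.60-fold) and WNT11 (1.58-fold) led them, by the smaller of the 2 fold changes. The other probe sets of SULT1A2 were higher in treated T84 than in Caco-2 (log2 fold changes of 1.30 and 0.38), so its place here rests on 1 probe set of a cross-hybridising family. Against untreated T84, the limma calls (n = 3 per group) of GALC, SULT1A2 and WNT11 were lost on leaving out single arrays: GALC without treated replicate 2 or 3 (adjusted p = 0.08 and 0.0659), SULT1A2 without treated replicate 2 or 3 or untreated T84 replicate 1 or 3 (0.0504 to 0.0592), and WNT11 without treated replicate 1 or 2 or any untreated T84 array (0.0546 to 0.0761). GALNT11 lost its call without the 3 arrays that deviated together (log2 fold change -0.60, adjusted p = 0.054).

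Both comparisons share the treated arrays. Independent lists of these sizes would share 10.7 probe sets upward and 19.1 downward, and 100 simulations of unchanged groups gave means of 0 and 0.01. Neither number holds the effects and the shared arrays at once, and part of the excess may come from the shared arrays, which are too few to split. A further 20 probe sets were lower than in untreated T84 and higher than in Caco-2, and 3 the reverse. Leaving out single arrays moved the number lower than both to 19 without treated replicate 2, 23 without treated replicate 3, 24 without untreated T84 replicate 1 and 22 without untreated T84 replicate 3.

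**Figure D3:**
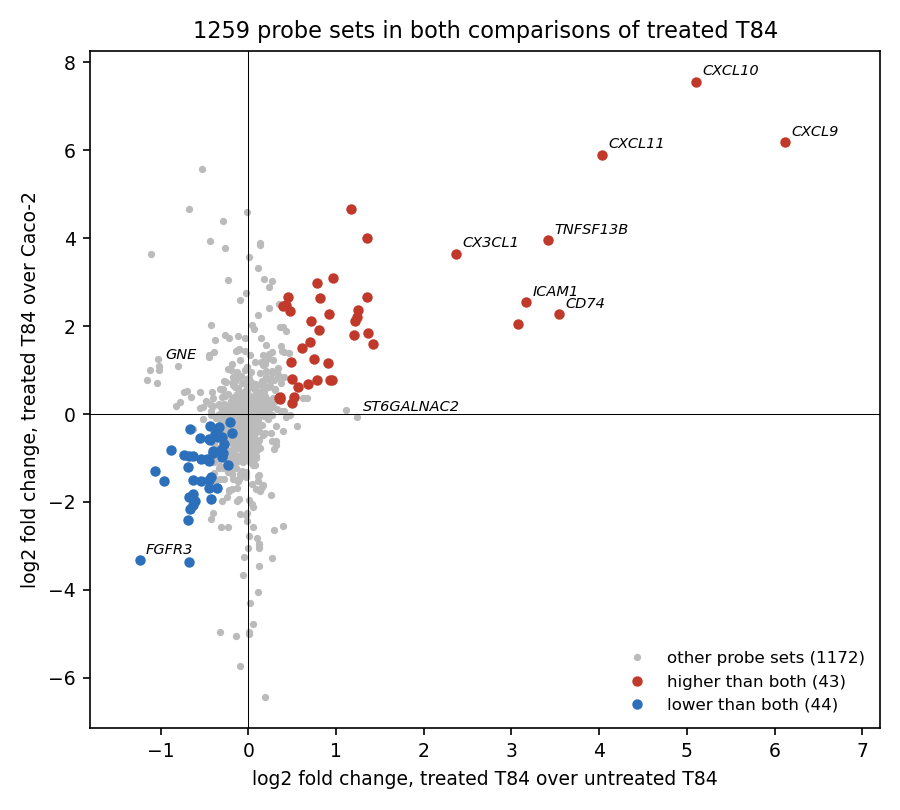
Log2 fold changes of 1259 probe sets for treated over untreated T84 (horizontal axis) and treated T84 over Caco-2 (vertical axis), each point 1 probe set. Red points (43) were higher and blue points (44) lower than both at an adjusted p below 0.05; CXCL9, CXCL10 and CXCL11 lie far to the upper right, ST6GALNAC2 at 1.24 and -0.06, and GNE at -1.02 and 1.10.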

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

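Leaving out 3 arrays together, the shared-deviation covariate and ribosomal centring were chosen after the result was seen. The others were chosen before the data were examined. Of 358 named gene values past the threshold, 305 stayed past it under every alternative that tested them, other than the 2-fold and 0.01 thresholds. Across the alternatives that tested them, 353 kept their sign. The filters on dim probe sets covered fewer than the 582 named gene values. The fit with only the main probe set of each gene was not used to retest them. Values left out of an alternative could not be lost there. Where no reason is given below, the cause was not tested.

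Against untreated T84, the main counts were 55 higher and 73 lower; against Caco-2, 244 and 330 for treated and 245 and 305 for untreated T84; against both, 43 and 44. The unmoderated test gave 48 lower in treated than in untreated T84 and 22 lower than both. Array weights gave 87 higher and 144 lower against untreated T84, 368 higher in treated T84 than in Caco-2, and 70 higher and 88 lower than both. With probe sets below the median signal left out, which leaves fewer to test, 191 were lower in untreated T84 than in Caco-2. By construction, requiring a 2-fold change lowered the counts: 19 and 9 against untreated T84, 94 and 121 for treated and 88 and 106 for untreated T84 against Caco-2, and 17 and 2 against both. An adjusted p of 0.01 gave 36 lower against untreated T84 and 17 lower than both.

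Leaving out 1 array at a time gave 45 to 70 higher and 40 to 108 lower against untreated T84, 211 to 297 and 294 to 343 for treated and 201 to 284 and 276 to 316 for untreated T84 against Caco-2, and 36 to 55 higher and 19 to 63 lower than both. Lower counts against untreated T84 outside 1.5 times the main count came without treated replicate 2 (40), treated replicate 3 (48) and untreated T84 replicate 3 (44). For those lower than both they came without treated replicate 2 (19) and 3 (23) and untreated T84 replicate 1 (24) and 3 (22). Of the named calls, 45 of 59 against untreated T84, 141 of 155 for treated and 138 of 144 for untreated T84 against Caco-2 held without each array in turn.

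The shared-deviation covariate gave 119 lower against untreated T84 and 72 lower than both. With 3 deviating arrays left out together, all counts stayed within 1.5 times. Ribosomal centring gave 43 lower against untreated T84, 19 lower than both, and 779 and 680 higher than Caco-2 in treated and untreated T84. By construction it moves every gene by the fall of the ribosomal genes, of which 29 of 41 and 23 of 41 were lower in T84. In treated T84 against Caco-2 it turned the sign of the calls of MAN2A2 (to 0.047), NANS (0.011) and ST3GAL3 (0.032). Values not past the test in the main fit turned sign and became calls. In treated T84 these were GALNT9 (0.20), NEU2 (0.23), ST8SIA2 (0.25), ST8SIA3 (0.26) and ST8SIA5 (0.25). In untreated T84 they were NEU2 (0.17), NEU3 (0.20), ST8SIA2 (0.19) and ST8SIA5 (0.20). The mean of all its probe sets reversed SULT1A2 against Caco-2, to 0.16 in treated and 0.64 in untreated T84, since 2 of its 3 probe sets were higher.

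Each comparison had 2 lists past the threshold. Camera with an estimated correlation called 0 in each, and fry called 5 against untreated T84 and 17 and 16 for treated and untreated T84 against Caco-2; shifting arrays to the same median left 1 for untreated T84 against Caco-2. Fry turned the direction of sialyltransferases (adjusted p = 0.0165 in treated and 0.00228 in untreated T84 against Caco-2) and of cytokine and growth factor receptors (0.00119 and 0.0036).

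A replicate block gave 50 and 59 against untreated T84, 225 and 309 for treated and 215 and 284 for untreated T84 against Caco-2, and 40 and 34 against both. Deviations of equal numbers correlated from -0.64 to 0.56 over all pairs of groups. Between treated and untreated T84 they correlated at 0.39, -0.02 and 0.56 for numbers 1, 2 and 3. There only treated replicate 3 correlated best with the untreated array of its own number. Whether the numbers pair the T84 arrays therefore stays open.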

Other observations

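The tests of GNE and ST6GALNAC2, of the growth factor families and of the shared deviation of both T84 arrays were chosen only after the result was seen. Further glycosylation genes separated the lines. HAS3, a hyaluronan synthase gene, was 6.39-fold higher in untreated T84 than in Caco-2 (95% confidence interval 5.77 to 7.08; limma adjusted p = 7.36e-09, n = 3 per group) and 6.00-fold higher in treated T84. Its other probe set did not pass (log2 fold changes of 0.40 and 0.39), so this difference rests on 1 of 2 probe sets. The O-GalNAc transferase gene GALNT4 was 4.17-fold (2.89 to 6.03) and GCNT3, which makes core 2 and core 4 O-glycans, 3.94-fold (3.20 to 4.85) higher in untreated T84, and the secretor gene FUT2 was 2.02-fold (1.58 to 2.59) higher. The chemokine gene CXCL14 was 4.73-fold lower (3.80 to 5.89). None of these 5 passed in treated against untreated T84.

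GNE was lower and ST6GALNAC2 higher in treated than in untreated T84. The normalization was tested with 4 scalings. Under these the smallest absolute log2 fold change of both genes was 0.96 and the highest limma adjusted p 0.00131. The scalings moved the median log2 fold change of all probe sets from -0.012 only to between -0.034 and 0.047. Changes as large as those of both genes could hardly be lost by such shifts, so other faults of the normalization stay untested. A single aberrant array was tested by leaving out each of the 9, and the highest adjusted p was 0.00633, with GNE between -1.12 and -0.92 and ST6GALNAC2 between 1.17 and 1.32. The second result argues against a single aberrant array. The first shows only that neither change depended on the choice among these scalings. Each gene had 1 named probe set, so an error of a probe set stays open.

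Treated T84 replicate 3, untreated T84 replicate 3 and Caco-2 replicate 1 deviated together from their groups, with a mean correlation of deviations of 0.60 (0.48 to 0.76). A trend with signal left by the normalization was tested by cyclic loess, after which the mean was 0.603, which argues against it. T84 RNA in Caco-2 replicate 1 would leave the T84 arrays alone. Such RNA therefore cannot account for the correlation of 0.56 between their deviations, which was part of the pattern already seen. For Caco-2 replicate 1 itself, such RNA was tested on 10 genes at least 8-fold higher in untreated T84. Their median difference from the other Caco-2 arrays was 0.16 (quartiles -0.02 and 0.31), against 0.08 over all named genes. That spread leaves T84 RNA open for this array, and no biological explanation was tested.

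Several genes of growth factor and developmental signalling families fell in treated against untreated T84, and these families were chosen after the largest falls were seen. Of 90 such genes, with a median log2 fold change of -0.02, 13 fell, among them FGFR3, FGF18 (-0.77 ± 0.10), BMP4 (-0.43 ± 0.09) and NOTCH1 (-0.42 ± 0.08), and 1 rose, FZD4 (0.40 ± 0.06), against 42 falls among 837 other genes (odds ratio 3.19, Fisher's exact test, two-sided, p = 0.00136). Genes are not independent, and camera gave p = 0.0682, or 0.543 with an estimated correlation. Without the 25 largest falls, 4 of 81 fell against 26 of 821 (odds ratio 1.59, Fisher's exact test, two-sided, p = 0.336), so a wider fall of this class and the pick of a few genes cannot be told apart.

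Other splits of the arrays were tested. The 10 splits of 6 arrays are too few for a share under 0.05; only 1 split, the real one, gave 128, 574 and 550 probe sets in the 3 comparisons, and the highest of the others was 0 in each. For lists, 3, 4 and 2 splits gave as many as the real 2 in treated against untreated T84, treated T84 against Caco-2 and untreated T84 against Caco-2, with highest others of 3, 3 and 2. Over 100 splits of the 9 arrays, 2 gave as many as the 43 probe sets higher than both and 2 as many as the 44 lower, the real split included. The other, at 273 and 179, set the 3 Caco-2 arrays apart and points to the structure of the lines. Splits that mix the lines count their differences as spread, so these numbers do not settle whether chance is excluded.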
